A study of Mus musculus with 98 samples.

How the data were processed

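The series reports RNA-seq and chromatin immunoprecipitation sequencing of mouse CD4 T cells with gain or loss of STAT5. Per the labels' protocols, naive CD4 T cells were sorted from pooled spleen and lymph nodes of C57BL/6 mice and stimulated with antibodies to CD3 and CD28. STAT5-deficient cells came from mice with floxed Stat5a and Stat5b and Cd4-Cre. Sets 2, 3 and 5 were transduced with retroviral vectors and then given human IL-2, per the labels' protocols. RNA was selected by poly(A) tail, per the labels' protocols.

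The deposited RNA-seq values are read counts per gene, made by the authors with TopHat2, Bowtie2 and HTSeq on mouse genome mm9, per the submitters' processing notes, which give no versions. The counts are whole numbers, 1 table per set, and 0 of 47 replicate pairs are identical. In sets 4 and 6, 27 rows whose names a spreadsheet had turned into dates could not be traced to a gene and were left out. They hold at most 0.27% of a library's counts. In sets 1 and 3, 253 symbols lacked the hyphen that the other tables carry and were given it back. Of 509 symbols in the gene lists used here, 25 are absent from the tables.

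The peak lists come from HOMER findPeaks, per the file headers, while the submitters' processing notes name MACS2, and the headers were followed. The STAT5 samples used antibodies to STAT5A and STAT5B, per the labels' protocols, while the directories named in the lists say STAT5b alone, per the file headers. Which form was precipitated in each replicate is not settled. In replicate 2 the deposited lists give peak height as a normalised signal in tags and a fold ratio over input, per the file headers, and replicate 1 lists carry no heights. The headers record Poisson thresholds of 1e-14 and 1e-17 for STAT5 and 1e-14 and 1e-18 for p300 in replicates 1 and 2, and 1e-06 and 1e-03 for STAT5 and 1e-06 and 1e-05 for p300 over input. They give 16.2 and 6.4 M tags for STAT5 and 18.6 and 17.0 M for p300, per the file headers. The histone mark and input samples are not analysed here. No genome annotation for mm9 was at hand, so peaks were not linked to genes and the planned test of STAT5-bound genes could not be run.

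Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with the groups, libraries were scaled with TMM, and a quasi-likelihood model with 1 mean per group was tested with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. Sets 2, 3 and 5 share 1 model (52 libraries, 26 groups, 16359 genes), and sets 1, 4, 6 and 7 have their own (12262, 15299, 11942 and 12392 genes). Groups in the shared model keep their set, and a comparison that spans sets averages the within-set differences. The common biological coefficient of variation was 0.064, 0.159, 0.24, 0.096 and 0.068 in sets 1, 2 with 3 and 5, 4, 6 and 7. With 2 libraries in most groups, the spread within a group rests on the other groups of its model.

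The self-test gave counts drawn from the real means and library sizes a 2-fold change in 200 genes. The edgeR test recovered 95% for IL-2 against rest, 76% for STAT5 loss with control vectors, 74.5% for MYC in deficient cells, 63.5% for Th0, 89.5% for the average of set 4, 86.5% for Treg cells and 90% for the Stat5a-null genotype. The simulated coefficient of variation, a median over genes, was 0.043, 0.107, 0.144, 0.035 and 0.046 in the 5 models, below the common values above. Recovery is thus overstated for genes with more spread.

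Gene lists were tested with camera in limma 3.58.1 with its preset correlation of 0.01, and a second time with the correlation estimated from the data. In all, 29 lists, on metabolism, growth, T cell subsets, stress and other cell types, met 31 comparisons. Camera ran where at least 5 members were tested, which left 28 lists, since polyamine synthesis never had 5. Of 851 list tests, 362 were called with the preset and 30 with the estimate, and the text gives the second value beside the first or alone. The second form also rests on the residual degrees of freedom of the model, only 4, 2 and 3 in sets 1, 6 and 7. A call lost there can come from few libraries and not only from correlation between genes. "Adjusted over the list alone" means that the adjustment ran over the members of that list instead of all genes.

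Genes are named in the text by a fixed rule. It takes Stat5a, Stat5b, Il2ra, Myc and Akt1 wherever tested, up to 8 called genes per direction with the largest fold change among those whose libraries do not overlap between groups and whose mean is at least 4 in log2 CPM (unnamed predicted transcripts left out), and up to 4 members of a list with the largest change. Stat5a and Stat5b are close paralogs, and overlapping or antisense genes cannot be told apart where counting did not use strand, so values of such genes are uncertain.

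Replicate numbers were checked for pairing by correlating deviations from group means. In groups of 2 libraries the deviations of replicates 1 and 2 mirror each other. Each correlation there is thus counted once under each number, and the pairs are not independent. In set 2 (30 pairs; correlation 0.11 to 0.42, median 0.24) and set 4 (90 pairs; 0.11 to 0.75, median 0.4) each pair of same-numbered libraries passed 0.1, so the numbers pair the samples there. In these sets the number goes with the sex of the mouse, read from Xist and the Y-linked Ddx3y. The main counts come from the model without this pairing, and counts with a replicate block are given further on. Sets 1, 3, 5 and 7 did not pass. The check asks for at least 3 such pairs, and set 6 has 2, too few to decide. Being mirrored, these 2 pairs give the same value, 0.58.

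Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a replicate block, a fit of only the libraries compared, and leaving out each library in turn. The comparisons, lists, tests and the first 215 of these alternatives were written before the data were examined. The 5 doubted libraries are 1 with transcripts of both sexes, 2 with Stat5a above the other deficient libraries, 1 rich in ribosomal RNA (set 5 STAT5-deficient with STAT5 and AKT, replicate 1) and 1 with counts in many more genes than others. Fits without them, with sex as a covariate in set 1 and with set 7 thinned to its smallest total were chosen after seeing the data, as was leaving out 1 library in the overlaps of gene lists. Peak overlaps were counted in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, at 1 shared base or more, and set against 1000 random shifts. Figures were drawn with matplotlib 3.10.9.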

Results

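The series holds 98 samples from mouse CD4 T cells, of which 88 RNA-seq libraries in 43 groups and 4 chromatin immunoprecipitation peak lists are used here. STAT5 is the transcription factor pair, encoded by Stat5a and Stat5b, that the interleukin-2 (IL-2) receptor switches on. The libraries form 7 sets of cultures. Set 1 compares activated cells rested without cytokine with cells given IL-2, at 3 libraries per group, and all other groups hold 2. In sets 2, 3 and 5, wild-type and STAT5-deficient cells carry control, STAT5, CD25, MYC or AKT vectors, alone or in pairs, and receive IL-2. Set 4 follows wild-type and STAT5-deficient cells in 5 culture conditions (Th0, Th1, Th2, Th17 and iTreg), set 6 regulatory T (Treg) cells before and after IL-2, and set 7 cells with reduced Stat5a and Stat5b gene dose. Counts per library ran from 3.9 M to 49.1 M, with a median of 16.8 M. The labels do not say whether replicates are separate animals. In sets 2 to 6 replicates 1 and 2 carry transcripts of opposite sex, apart from 1 library with both. They thus come from different mice there, and the spread within a group includes a sex difference. For set 7 and part of set 1 the question stays open. The p-values measure only the spread between these samples.

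Among the cells with vectors, Stat5a stood at 69.3 to 99.6 CPM in the 16 wild-type libraries without a STAT5 vector, and Stat5b at 138.6 to 209.7. In the 16 STAT5-deficient libraries without that vector, Stat5a was at 1.0 to 19.2 and Stat5b at 0.6 to 8.4. The 2 highest Stat5a values there, 19.2 and 18.4, belong to set 5 replicate 1 with control vectors and with MYC, and the other 14 libraries held 1.0 to 5.3. With the STAT5 vector, Stat5a reached 406.2 to 1169.2 in STAT5-deficient and 138.4 to 608.0 in wild-type libraries. In set 4, Stat5a was at 1.8 to 4.8 and Stat5b at 0.6 to 4.0 in STAT5-deficient libraries, against 150.7 to 566.3 and 186.6 to 447.2 in wild type. Set 7 held Stat5a at 189.0 to 191.0 in wild type, 4.7 to 5.0 in the Stat5a-null Stat5b-heterozygous genotype, and 98.7 to 110.7 in the Stat5b-null Stat5a-heterozygous genotype. Stat5b in the same groups was at 259.0 to 275.4, 54.6 to 57.9 and 29.0 to 31.9. Genotypes are named as in the labels, and Stat5b in the Stat5b-null libraries lay well above the 0.6 to 8.4 of STAT5-deficient cells with vectors. The counts do not show whether that transcript is intact.

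**Figure D1:**
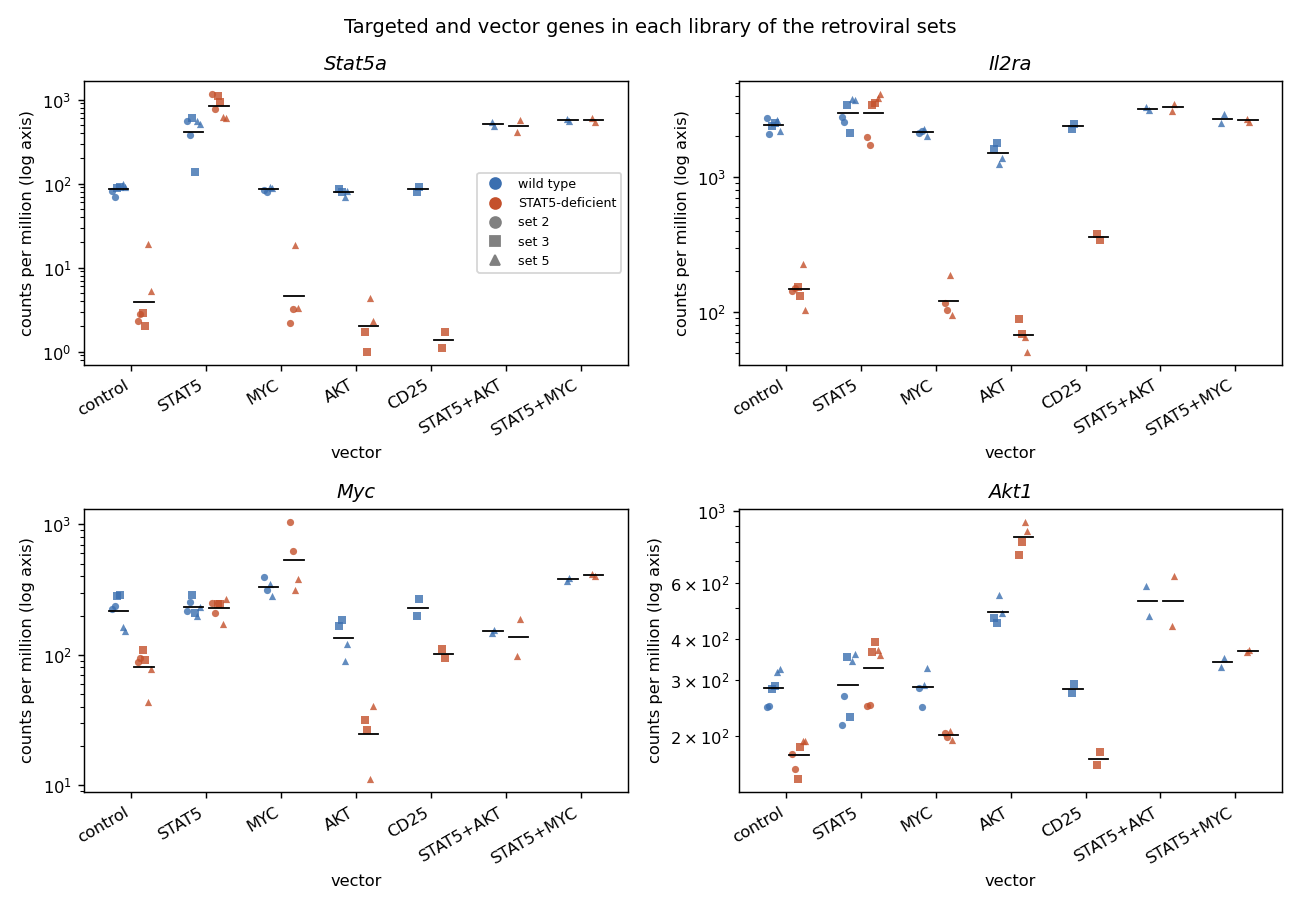
CPM (log axis) of Stat5a, Il2ra, Myc and Akt1 in each library of sets 2, 3 and 5, by vector and genotype (WT, wild type; KO, STAT5-deficient). Marker shape gives the set and the black bar the geometric mean.

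IL-2 given after the rest raised its own receptor chain Il2ra, which encodes CD25 (log2 fold change ± standard error 3.30 ± 0.06; from 229 ± 7.7 to 2250 ± 68 CPM, mean ± SD), and the cytokine-signalling suppressor Socs2 (7.38 ± 0.10). Lrrc32, which holds TGF-beta on the cell surface (7.01), the cytokines Lta (3.94) and Tnf (3.78), the oxygen sensor Egln3 (4.14) and Myc (1.02 ± 0.07) rose with it. Glycolysis genes rose throughout (20 of 20; median 1.47), led by the glucose transporter Slc2a1 (2.92), the lactate exporter Slc16a3 (2.70) and Hk2 (2.38). Cholesterol synthesis rose in 21 of 21 genes (median 1.75), with Lss at 2.71, and IL-2-STAT5 targets in 18 of 20. Interferon-stimulated genes fell in 14 of 14 (median -3.28), with Mx1 at -6.46 and Rsad2 at -5.02, and the naive and follicular helper genes Bcl6 (-3.14) and Cxcr5 (-4.45) fell too. Of 12262 genes tested with edgeR, 9942 were called at an adjusted p below 0.05, 4995 of them higher and 4947 lower (4926 and 5017 with RLE scaling). The counts were 20 for glycolysis, 21 for cholesterol synthesis, 18 for IL-2-STAT5 targets and 14 for interferon genes adjusted over the list alone. Camera kept none of these lists once the correlation between genes was estimated: adjusted p = 0.31 with an estimated correlation for glycolysis, 0.22 for cholesterol synthesis, 0.22 for IL-2-STAT5 targets and 0.22 for interferon-stimulated genes. IL-2 cells were cultured about 18 h longer than rested cells, so time in culture is part of this comparison. The ribosomal RNA transcript Rn45s stood at 2580.5 to 3712.0 CPM in rested and 1088.6 to 1313.2 in IL-2 libraries. A difference in RNA preparation is therefore not excluded here. Antigen-presenting and B cell markers were lower after IL-2 (Cd74 -4.52, Cd79a -2.43, Cd68 -2.49).

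Loss of STAT5 in IL-2 cultures with control vectors took down Il2ra (-4.24 ± 0.16; from 2570 ± 270 to 137 ± 37 CPM), Lrrc32 (-6.16), Egln3 (-5.95), Socs2 (-5.19), the laminin chain Lama5 (-5.34) and Myc (-1.64 ± 0.18). Glycolysis fell in 20 of 20 genes (median -2.91), with Tpi1 at -3.78, Aldoc at -3.89 and Hk2 at -3.53. Cholesterol synthesis fell in 21 of 21 (median -2.21; Fdps -3.91), and the desaturases Scd1 (-6.18) and Fads2 (-4.73) fell with it. Among IL-2-STAT5 targets, 19 of 20 were lower, with the granule protease Gzmb at -4.46 and the kinase Pim1 at -3.84. Ribosome biogenesis was lower in 28 of 29 genes (median -1.35). Genes that rose were the innate receptor Nod1 (4.48), the MYC antagonist Mxd4 (4.11), the transcription factors Sox4 (3.87) and Ikzf3 (3.13), and the Tfh and naive genes Cxcr5 (3.61), Bcl6 (3.48) and Tcf7 (2.25). The edgeR count was 9779 of 16359 genes, 4731 higher and 5048 lower, from 6 libraries per genotype in 3 sets. With RLE scaling 5094 were higher and 4781 lower, so the lean depends on scaling. Adjusted over the list alone the calls were 20 for glycolysis, 21 for cholesterol synthesis, 19 for IL-2-STAT5 targets and 28 for ribosome biogenesis. Camera gave adjusted p = 0.049 with an estimated correlation for glycolysis and for cholesterol synthesis, 0.024 for IL-2-STAT5 targets and 0.14 for ribosome biogenesis. Myeloid and antigen-presenting cell markers were higher in STAT5-deficient cultures (Cd68 2.74, Itgam 2.86, Cd74 2.57). Whether these come from other cells or from the T cells was not tested.

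The genes that IL-2 raised and those that fell without STAT5 overlapped, in libraries the 2 comparisons do not share. Of 4993 genes raised by IL-2 and tested in each model, 4239 (84.9%) were lower on STAT5 loss, against 8.48% of the other genes (Fisher odds ratio 60.6), and 54 were higher. Il2ra, Socs2, Lrrc32 and Egln3 are among the 4239. Of 4945 genes that IL-2 lowered, 3658 (74%) were higher on STAT5 loss, against 7.36% of the others (odds ratio 35.8), and Nod1, Mxd4 and Bcl6 are among them. Measured against the set 4 average of STAT5 loss, where cultures ran 3 days, 19.8% of the genes raised by IL-2 were lower, against 9.52% of the others. Genes are not independent replicates, so these tests describe lists.

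Returning STAT5 to deficient cells brought Il2ra up by 4.43 ± 0.16 (from 137 ± 37 to 3150 ± 1200 CPM), along with Socs2 (5.36), the cytokine Lif (6.46), Cd24a (5.44), the amino acid-sensing GTPase Rragd (5.15), Foxp3 (4.02) and Myc (1.64 ± 0.18). Ribosome biogenesis rose in 29 of 29 genes (median 2.01), IL-2-STAT5 targets in 18 of 20 and cholesterol synthesis in 19 of 21 (median 0.99). For glycolysis, 16 genes rose and 2 fell (median 1.5). Nod1 (-4.32), the PI3K inhibitor Pik3ip1 (-3.63), Bcl6 (-2.86) and Cxcr5 (-3.69) fell. The vector reads on Stat5a (7.79 ± 0.33) and also on its paralog Stat5b (4.00). This made 10089 calls, 5224 higher and 4865 lower (4997 and 5203 with RLE scaling). List by list, 29 genes were called adjusted over the list alone for ribosome biogenesis, 18 for IL-2-STAT5 targets, 19 for cholesterol synthesis, and 16 up and 2 down for glycolysis. Camera gave adjusted p = 0.15 with an estimated correlation for ribosome biogenesis, 0.11 for IL-2-STAT5 targets, 0.21 for cholesterol synthesis and 0.24 for glycolysis. Myeloid and antigen-presenting cell markers were lower with the vector (Cd68 -1.84, Cd74 -1.08), and whether that reflects fewer other cells was not tested.

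In wild-type cells the same vector made 2823 calls (1445 higher, 1378 lower), and 1731 without set 3 STAT5 replicate 1. Stat5a rose by 2.39 ± 0.24, the Treg factor Foxp3 by 2.42, Irf4 by 2.34 and the receptor Fzd7 by 2.79, while Gzmb (-1.40) and Rasgrp2 (-1.51) fell. Set 3 STAT5 replicate 2, part of this comparison, held 3.9 M counts and Stat5a at only 138.4 CPM. Markers of STAT5-deficient control cells stood in that library at a median share of 25.5%. Il2ra was not called (0.31 ± 0.14, adjusted p = 0.14), but was called at 0.43 without set 3 STAT5 replicate 2 or without the 5 doubted libraries. Cholesterol synthesis was lower in 16 of 21 genes (18 adjusted over the list alone) and ribosome biogenesis higher in 18 of 29 (25 adjusted over the list alone), each with adjusted p = 0.67 with an estimated correlation. The vector effect differed between genotypes for 7425 genes, larger in deficient cells for Lrrc32 (5.80), Socs2 (5.13), Lif (4.37) and Il2ra (4.12 ± 0.21), and more negative there for Mxd4 (-3.68) and Pdcd1 (-2.71). IL-2-STAT5 targets differed in 18 of 20 genes (18 adjusted over the list alone; adjusted p = 0.032 with an estimated correlation). Stat5a rose less in wild type, which has its own STAT5, so dose and genotype are not separated.

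Set beside wild-type cells with control vectors, deficient cells with the STAT5 vector were not called for Il2ra (0.19 ± 0.14, adjusted p = 0.31) or Myc (0.00 ± 0.17, adjusted p = 1). They stayed lower for Gzmb (-5.14), Scd1 (-3.33), the glucose transporter Slc2a3 (-3.20) and Aldoc (-3.20), and higher for Sox4 (4.59), Foxp3 (3.84) and Myb (3.02). Glycolysis was below wild type in 19 of 20 genes (median -1.21; 20 adjusted over the list alone), cholesterol synthesis in 20 of 21 (-1.30; 20 adjusted over the list alone) and hypoxia-associated genes in 13 of 14 (-1.39; 13 adjusted over the list alone). Those 3 lists kept adjusted p = 0.045, 0.018 and 0.015 with an estimated correlation. Ribosome biogenesis was above wild type in 26 of 29 genes (27 adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). In all, 6246 genes differed. Stat5a stood above wild type (3.20) and Stat5b below it (-2.19), so the STAT5 dose was not that of wild type.

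**Figure D2:**
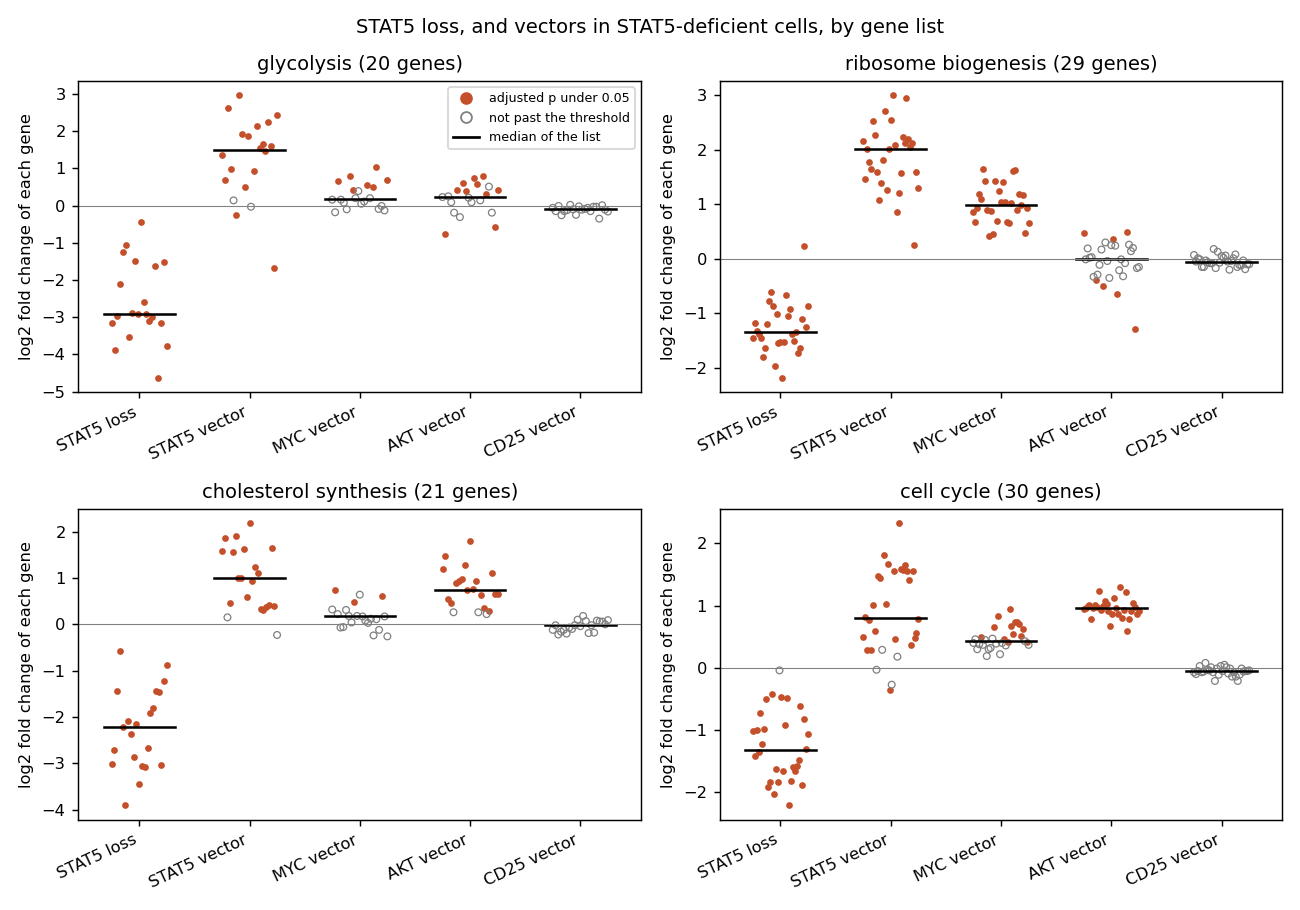
Log2 fold changes of single genes in 4 lists for STAT5 loss and for the STAT5, MYC, AKT and CD25 vectors in STAT5-deficient cells. Filled points have an adjusted p below 0.05, open points do not, and the black line is the list median.

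MYC, the growth regulator whose transcript falls without STAT5, was given by vector to STAT5-deficient cells (Myc 2.90 ± 0.23; from 69.1 ± 23 to 550 ± 310 CPM). It raised the polyamine enzyme Srm (2.11), the amino acid transporter Slc7a5 (1.74) and the nucleolar genes Gnl3 (1.65), Ppan (1.63) and Pus7 (1.66). Ribosome biogenesis rose in 29 of 29 genes (median 0.98), nucleotide synthesis in 18 of 20, serine and one-carbon metabolism in 9 of 12 and amino acid transporters in 8 of 13. Glycolysis rose in 7 of 20 genes with a median of 0.18, and Il2ra was not called (-0.30 ± 0.17, adjusted p = 0.31), but was called at -0.56 without set 5 control replicate 2. Id2 (-0.84), the cortisol-activating enzyme Hsd11b1 (-0.87) and Tnfsf4 (-0.79) fell. There were 2039 calls, 1572 higher and 467 lower (1506 and 781 with RLE scaling), and 1073 without set 2 control replicate 2, 1359 without set 2 MYC replicate 1 and 1235 without set 5 control replicate 2. Set 2 deficient control replicate 2 held the ribosomal RNA transcript Rn45s at 10453.9 CPM, against 1609.9 to 2723.1 in the other set 2 deficient control and MYC libraries. Adjusted over the list alone the counts were 29 for ribosome biogenesis, 20 for nucleotides, 9 for one-carbon metabolism, 11 for transporters and 8 for glycolysis. Camera gave adjusted p = 0.025 with an estimated correlation for ribosome biogenesis and for nucleotides, 0.031 for one-carbon metabolism and for transporters, and 0.52 for glycolysis.

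Wild-type cells, which already express Myc, gave 130 calls with the MYC vector (100 higher). Myc itself was not called at 0.76 ± 0.21 (adjusted p = 0.086), but was with DESeq2, a replicate block, no doubted libraries or only the libraries compared (0.76 to 0.77). Srm rose by 0.63, the nucleolar gene Utp20 by 0.71 and Polr1b by 0.65, and Dapl1 fell (-0.81). Ribosome biogenesis rose in 11 of 29 genes (26 adjusted over the list alone; adjusted p = 0.044 with an estimated correlation). The MYC effect differed between genotypes for 206 genes, stronger without STAT5 for Myc (2.14 ± 0.31), Srm (1.48), Bcat1 (1.49) and Ifrd2 (1.68). Myc itself thus rose more in deficient cells, so dose and genotype are not separated. Nucleotide synthesis differed in 8 of 20 genes (15 adjusted over the list alone; adjusted p = 0.049 with an estimated correlation). The 130 calls became 438 with DESeq2, 413 without the 5 doubted libraries and 228 with a replicate block. Without 1 library it was 4 for set 2 MYC replicate 2, set 5 control replicate 2 or set 5 MYC replicate 1, 11 for set 2 control replicate 1, 24 for set 5 control replicate 1 and 63 for set 5 MYC replicate 2. Srm and Dapl1 lost their call in 7 of these 8 fits, Polr1b in 4 and Utp20 in 3. The 206 genotype differences became 410, 643 and 301 in the same order as the first 3 of these, and 1 when only the libraries compared were fitted. Leaving out 1 of the 16 libraries gave from 39 (set 5 STAT5-deficient control replicate 2) to 357 (replicate 1 of that group).

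AKT, the kinase downstream of PI3K, was given to STAT5-deficient cells in the same way (Akt1 2.26 ± 0.11; from 158 ± 18 to 759 ± 96 CPM). The trafficking genes S1pr1 (-2.85), Ccr7 (-2.79) and Klf2 (-2.74) fell, as did Igf1r (-3.23), Pim2 (-2.67), Ctla4 (-2.62), Il2ra (-1.14 ± 0.18) and Myc (-1.40 ± 0.23). FOXO-associated genes fell in 11 of 14 (median -1.29), Treg-associated genes in 7 of 11 and naive and Tfh genes in 10 of 14. Cell cycle genes rose in 30 of 30 (median 0.97), cholesterol synthesis in 18 of 21 (0.75) and interferon-stimulated genes in 11 of 14 (Rsad2 2.85; 1.96 and not called without set 5 AKT replicate 1). Glycolysis was mixed, with 8 genes higher and 2 lower (median 0.24; camera adjusted p = 0.072, and adjusted p = 0.65 with an estimated correlation). Calls numbered 4635, 2782 higher and 1853 lower (2410 and 2277 with RLE scaling). Member counts adjusted over the list alone were 13 for FOXO, 7 for Treg, 10 for naive and Tfh, 30 for cell cycle, 20 for cholesterol and 13 for interferon genes. Camera gave adjusted p = 0.0019 with an estimated correlation for FOXO genes, 0.0011 for Treg genes, 0.022 for naive and Tfh genes, 0.063 for cell cycle and for cholesterol synthesis, and 0.51 for interferon genes.

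In wild-type cells the AKT vector lowered the trafficking regulator Klf2 too, with 825 calls (221 higher, 604 lower). Rasgrp2 (-2.51) and Klf2 (-1.94) fell, while Fosl2 (1.36), Gzmb (1.31) and the asparagine enzyme Asns (1.19) rose. FOXO-associated genes fell in 9 of 14 (10 adjusted over the list alone; adjusted p = 0.00063 with an estimated correlation), and ATF4 and stress response genes rose in 4 of 15 (5; 0.037; Chac1 2.10). Genotype changed the AKT effect for 1727 genes, 1216 up and 511 down (1016 and 685 with RLE scaling), more positive without STAT5 for Akt1 (1.62) and the ATP receptor P2rx7 (2.11), and more negative for Ndrg1 (-2.21) and Il7r (-1.83). Cell cycle genes differed in 30 of 30 (median 1.0; 30 adjusted over the list alone; adjusted p = 0.056 with an estimated correlation). The 825 wild-type calls became 1540 when only the libraries compared were fitted, 530 without set 3 control replicate 1 and 376 without set 5 control replicate 1. Gzmb lost its call in 6 of the 8 fits without 1 library and Chac1 in 4. The 1727 became 1132 without set 5 wild-type control replicate 1 and 865 without set 5 wild-type AKT replicate 2. The vector raised Akt1 by 2.26 in deficient cells and by 0.64 in wild type, so dose and genotype are not separated.

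CD25, the receptor chain encoded by Il2ra, was supplied by vector, and no gene was called in edgeR with the settings used throughout. In STAT5-deficient cells Il2ra was at 1.31 ± 0.25 (adjusted p = 0.09; from 127 ± 15 to 315 ± 22 CPM), well short of the 2093.8 to 2752.7 of wild-type control libraries. Calls were 0 in deficient cells, 0 in wild type and 0 between genotypes, with unadjusted p below 0.05 for 202, 157 and 205 genes. Il2ra was called in deficient cells (1.31 to 1.32) with DESeq2, no low-count filter, a replicate block, only the libraries compared or no doubted libraries, each time as the only gene. DESeq2 gave 0 calls in wild type. Glycolysis leaned down in wild type with the CD25 vector (median -0.32; 0 members called and 0 adjusted over the list alone; camera adjusted p = 2e-15, and adjusted p = 0.13 with an estimated correlation). In the self-test, 70.5% of 200 genes changed 2-fold were recovered for the deficient-cell comparison, but with a spread of 0.107 where the fit gave 0.159, so real changes could pass unseen.

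Pairs of vectors show what MYC and AKT add to STAT5. In deficient cells that had the STAT5 vector, AKT changed 62 genes (25 higher), among them Akt1 (0.64) up and the interferon-induced Gbp2 (-1.29) and the zinc transporter Slc39a8 (-1.21) down. Replicate 1 of the cells with STAT5 and AKT held 20.9% of its counts in Rn45s and 4.4% in Lars2, against 0.1 and 0.0% in replicate 2, and without it 9 genes were called. In wild type it changed 80, lowering Pim2 (-1.38), Igf1r (-1.16), Dgka (-1.08) and Bach2 (-1.03). MYC on top of STAT5 changed 984 genes in deficient cells (695 higher), raising Asns (1.45), the folate carrier Slc19a1 (1.14) and Srm (1.12), and lowering Ahnak (-1.37). Ribosome biogenesis rose in 24 of 29 genes (29 adjusted over the list alone; adjusted p = 0.062 with an estimated correlation). The wild-type count was 732 (165 higher and 567 lower; 286 and 419 with RLE scaling), with Asns (1.18) and C1qbp (0.92) up and Slfn1 (-1.58) down. Other settings moved these counts by more than 1.5-fold: DESeq2 gave 127, 179, 1772 and 1385, and fitting only the libraries compared gave 4, 126, 2598 and 2214, in the order listed. Leaving out 1 library gave 9 to 340 and 1 to 10 for AKT, and 21 to 522 and 7 to 844 for MYC, so each of the 4 counts rests on single libraries. Akt1 in deficient cells (0.54 to 0.75) and Igf1r and Bach2 in wild type were no longer called, whichever of the 4 libraries was left out. Asns in wild type lost its call in 3 of 4 such fits (0.86 at the lowest), Asns and Srm in deficient cells, Slc39a8 and Pim2 in 2, and C1qbp, Slfn1, Dgka and Ahnak in 1. Fitting only the libraries compared took the call from Akt1, Gbp2 and Slc39a8, and no low-count filter from Akt1.

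STAT5 added to the other vectors changed more genes in deficient cells, but the doses differed. Stat5a went from 4.4 and 2.3 to 406.2 and 576.2 CPM on top of AKT. On top of MYC it went from 18.4 and 3.3 to 605.2 and 538.7. AKT added to STAT5 moved Akt1 from 370.0 and 358.7 to 439.4 and 631.2 CPM. MYC added to STAT5 moved Myc from 172.9 and 268.7 to 418.4 and 401.0. Dose and kind of vector are thus not separated. On top of AKT, STAT5 changed 7278 genes in deficient cells (3809 higher, 3469 lower). It raised Il2ra (6.11 ± 0.31), Lif (7.79), Socs2 (6.78), the transferrin receptor Tfrc (5.88) and Myc (2.63 ± 0.33) and lowered Mxd4 (-4.42). The library rich in ribosomal RNA is 1 of the 2 with STAT5 and AKT, and without it the count stayed within 1.5-fold. IL-2-STAT5 targets rose in 19 of 20 genes (median 3.00; 19 adjusted over the list alone; adjusted p = 0.0062 with an estimated correlation). On top of MYC, STAT5 changed 8978 genes (4688 higher, 4290 lower). With RLE scaling 4401 were higher and 4697 lower. The imprinted transcript H19 (7.90), Ifitm3 (6.20) and Il2ra (4.57 ± 0.28) rose with STAT5 on top of MYC, and Pik3ip1 (-4.84) fell. Glycolysis rose there in 18 of 20 genes and fell in 1 (median 2.20; 18 up adjusted over the list alone; adjusted p = 0.11 with an estimated correlation).

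How far each vector moved STAT5-dependent genes was read on a list from other libraries, the 1822 genes lower on STAT5 loss in set 4. Not all of them depended on STAT5 in the cultures with vectors. On STAT5 loss with control vectors 1169 (64.2%, against 29.4% of other genes) were lower and 195 (10.7%, against 33.5%) higher. In deficient cells the STAT5 vector raised 1023 of the 1822 (56.1%, against 31.5% of other genes, Fisher exact p = 2.2e-90). The median log2 fold change of the list was 0.49, and Il2ra, Socs2 and Lrrc32 were among the 1023. MYC raised 303 (16.6%, against 9.69%; median 0.10; Fisher exact p = 1.9e-17). AKT raised 414 (22.7%, against 18.1%; Fisher exact p = 2.7e-06; 18.2% and no longer called without deficient Th1 replicate 2) and lowered 342 (18.8%, against 11.5%), with a median of -0.00. CD25 raised 0, with a median of -0.03. These shares rest on unequal numbers of libraries: 6 per group for STAT5, 4 for MYC and for AKT, and 2 for CD25. Genes are not independent replicates, so the Fisher tests describe lists and not the spread between libraries. With CD25 no gene was called at all, so its share of the list had to be 0. For MYC and AKT the direction turned when the list was held to the 451 genes at least 2-fold lower: 4.21% rose with MYC against 10.7% of other genes, and 7.1% with AKT against 19%. The STAT5 vector raised 53.7% of those 451.

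Averaged over the 5 culture conditions, STAT5 loss lowered the transcription factor Batf3 (-4.15), Lama5 (-4.07), Socs2 (-3.89), Lta (-3.69) and Il2ra (-0.70 ± 0.12). The opioid peptide gene Penk (4.21), Tnfsf4 (3.00) and Bcl6 (3.15) rose. Ribosomal protein genes were lower in 34 of 35 (median -0.44; 34 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). Th17-associated genes were higher in 8 of 10 (8 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). The average called 4152 of 15299 genes, 2304 higher and 1848 lower. An F-test found 2769 genes whose STAT5 effect differed between conditions, with 17 of 20 glycolysis genes, 17 of 20 IL-2-STAT5 targets, 12 of 14 hypoxia-associated genes and 0 of 35 ribosomal protein genes among them. Il2ra (adjusted p = 0.0028), Myc (adjusted p = 0.022) and Hk2 (adjusted p = 0.0014) are on that list. DESeq2 gave 4684 in place of 2769, and leaving out wild-type iTreg replicate 1 gave 1750.

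In Th0, where no cytokine was added, loss of STAT5 lowered Socs2 (-5.87), Egln3 (-4.95), the transglutaminase Tgm2 (-4.65), Lif (-3.03) and Il2ra (-1.58 ± 0.26) and raised Penk (3.42) and Tnfsf4 (2.64). Glycolysis was lower in 11 of 20 genes (median -0.77; 17 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation) and IL-2-STAT5 targets in 16 of 20 (17 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation). The count was 993, 583 higher. Genes that also mark NK or myeloid cells were higher there without STAT5 (Klrd1 3.24, Eomes 2.26, Cd68 1.64, Cd74 1.56), and whether other cells carry them was not tested. Without 1 library, Cd68 lost its call in 3 of 4 fits, Cd74 in 2 and Eomes in 1. In iTreg cultures, given TGF-beta, the effect was the widest of the 5, with 3457 calls. There Scd1 (-4.91), the kinase Sgk1 (-4.20), Lama5 (-4.48) and Il2ra (-1.72 ± 0.26) fell, and the integrin Itgae (5.77), Sox4 (4.81), Il17a (8.64), Il17f (4.49) and Bcl6 (3.61) rose. Il17a stood at 0.0 and 0.1 CPM in wild-type iTreg and at 18.6 and 38.4 without STAT5, so its fold change starts near 0. Glycolysis fell in 18 of 20 iTreg genes (median -1.89; 18 adjusted over the list alone), with adjusted p = 0.039 with an estimated correlation and 0.053 once replicate numbers were blocked. Cholesterol synthesis was lower in 17 of 21 iTreg genes (19 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation). DESeq2 gave 1635 calls in Th0, and leaving out any 1 of its 4 libraries gave 423 to 594. Such markers went both ways in iTreg (Cd68 1.36, Klrd1 -1.58, Eomes -1.41), and without 1 library Cd68 and Eomes lost their call in 2 of 4 fits and Klrd1 in 4. The iTreg count was 1550 and 2234 without wild-type replicates 1 and 2, and 2123 without STAT5-deficient replicate 1.

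Loss of STAT5 in Th1 cultures, which received IL-12, raised interferon-stimulated genes. They rose in 10 of 14 (median 1.92; 10 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), among them Ifi44 (5.07) and Ifit1 (3.59), beside the interferon-induced GTPases Tgtp2 (4.05) and Iigp1 (3.67) and the Th1 genes Tbx21 (1.98) and Ifng (1.74). Gzmb (-3.40) and Il24 (-4.13) fell, Il2ra was not called (0.17 ± 0.26, adjusted p = 0.78), and glycolysis was higher in 6 of 20 genes and lower in 1 (median 0.38; 8 and 2 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.73 with an estimated correlation). Markers of other cells went both ways in Th1 (Cd68 -2.56, Cd74 2.16, Klrd1 2.43), Cd68 was lower in Th2 (-1.82) and Cd74 higher in Th17 (2.05), which was not traced further. In Th2 cultures Il4 (-4.55), Batf3 (-4.35) and the motor protein Myo6 (-4.76) fell, and Il3 (3.66) and Tnfsf11 (4.15) rose. Th17 cultures lost Gzmb (-4.34), Il13 (-4.61), Gpr83 (-3.69) and Ikzf4 (-2.77) and gained Il17a (3.80), Il22 (2.84) and Bcl6 (3.24). Il13 was hardly expressed in Th17, at 0.7 and 3.4 CPM in wild type and 0.0 and 0.2 without STAT5. Treg-associated genes were lower there in 4 of 11 (8 adjusted over the list alone; adjusted p = 0.026 with an estimated correlation). Counts were 1796 in Th1, 1765 in Th2 (1137 higher and 628 lower; 1002 and 885 with RLE scaling) and 747 in Th17, and 2994 in Th2 with the replicate block. With DESeq2 they were 2816, 2626 and 1166, and with only the libraries compared 871 in Th1 and 803 in Th2. Leaving out 1 library brought the Th1 count to 488 and 1103 (wild-type replicates 1 and 2) or 687 (deficient replicate 1), and the Th2 count to 780 and 734 (deficient replicates 1 and 2). Ifng in Th1, Il4 in Th2 and Il13 and Il22 in Th17 lost their call in 3 of 4 such fits, and Tbx21 and Klrd1 in Th1, Cd68 in Th2 and Gpr83 in Th17 in 1. Ifng also lost it with DESeq2, Il13 with RLE scaling, and Il13 and Il22 with only the libraries compared. The Th17 count was 332 without wild-type replicate 2 and 318 and 266 without deficient replicates 1 and 2.

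The glycolysis effect was tested between conditions as well. It was lower in iTreg than in Th1 by a median of 2.40 (18 of 20 genes called; camera adjusted p = 2e-15, and adjusted p = 0.043 with an estimated correlation). It was lower in iTreg than in Th17 by 1.96 (17 of 20; camera adjusted p = 9.9e-16, and adjusted p = 0.041 with an estimated correlation). Th0 lay below Th1 with a median difference of -1.16 (13 of 20; adjusted p = 0.081 with an estimated correlation). It differed in 4 of 20 genes from Th2, 2 from Th17 and 8 from iTreg (adjusted p = 0.31, 0.18 and 0.15 with an estimated correlation), and Th2 from iTreg in 16 (adjusted p = 0.15 with an estimated correlation). Hk2 carried STAT5 effects of -1.63 in Th0 (not called when any 1 of the 4 libraries was left out), -2.99 in iTreg, and 1.10 in Th1, 0.11 in Th2 and 0.17 in Th17. The last 3 were not called, although Th1 was with DESeq2, no low-count filter or only the libraries compared. Replicate 2 of Th1 bears a Th2 cell-type label in each genotype. Its Tbx21 (70.4 and 289 CPM beside 65.8 and 250 in replicate 1) matches the Th1 titles, which were followed.

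**Figure D3:**
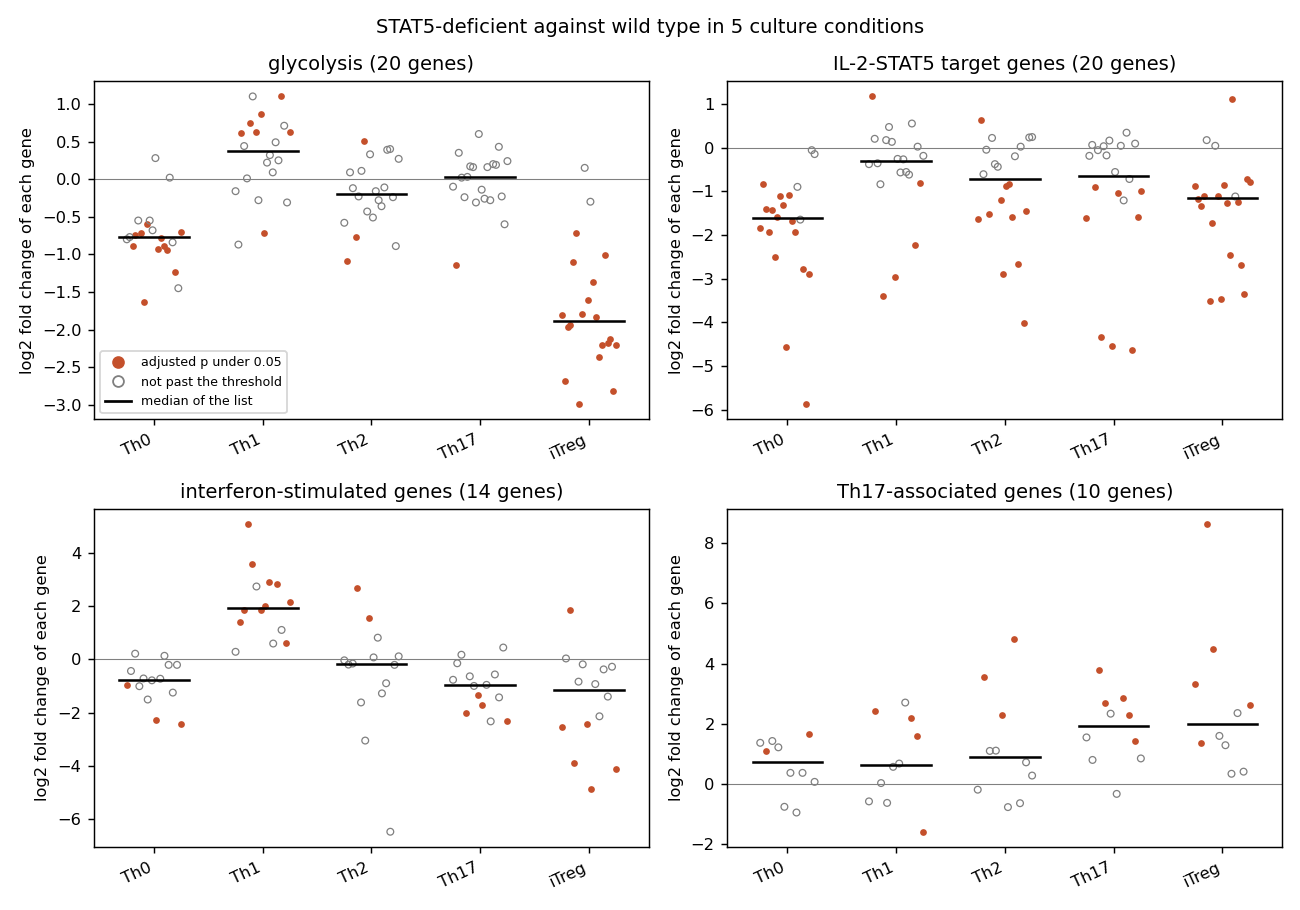
Log2 fold changes for STAT5 loss of single genes in 4 lists, by culture condition. Filled points have an adjusted p below 0.05, open points do not, and the black line is the list median.

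Treg cells cultured overnight with IL-2 were compared with Treg cells taken straight from the animal, so culture and cytokine cannot be told apart. Il2ra (1.39 ± 0.11), Lama5 (5.29), the AP-1 gene Fosl2 (4.05), Crem (3.37) and the fatty acid elongase Elovl6 (2.92) rose. The early-response genes Fos (-4.81) and Egr1 (-3.40), the Notch-pathway gene Dtx1 (-4.62) and Ifng (-5.60) fell. Ifng was low in each group, with a mean of 3.02 CPM before culture and 0.0464 after. Ribosomal protein genes fell in 33 of 35 (34 adjusted over the list alone), interferon-stimulated genes in 13 of 14 (13) and early-response and heat shock genes in 9 of 10 (9). Cholesterol synthesis rose in 13 of 21 genes (16 adjusted over the list alone) and IL-2-STAT5 targets in 15 of 20 (15). With an estimated correlation camera gave adjusted p = 0.61 for ribosomal proteins, 0.61 for interferon genes, 0.61 for early-response genes, 0.61 for cholesterol synthesis and 0.6 for IL-2-STAT5 targets. The count was 3701 of 11942 (1821 higher, 1880 lower) and 2451 with DESeq2. B cell transcripts were present (Cd79a at 27.5 to 87.6 CPM across the 4 libraries), and the myeloid and NK markers Lyz2 (-1.61), Itgam (-1.12) and Eomes (-1.16) fell, the last 2 without a call in DESeq2. Whether a loss of other cells adds to the falls in Ifng and interferon genes was not tested.

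Lowering the STAT5 gene dose, with 1 Stat5b or 1 Stat5a copy left, took down IL-2-STAT5 target genes as well. In the Stat5a-null genotype, Lrrc32 (-8.71), Tgm2 (-8.23), Lama5 (-7.26), Egln3 (-7.15), Socs2 (-6.11) and Il2ra (-1.38 ± 0.07) fell, and the adhesion gene Cadm1 (6.57), Arc (3.93) and Crtam (3.40) rose. In the Stat5b-null genotype the values were -8.21 for Lrrc32, -7.55 for Tgm2, -4.89 for Socs2, -1.42 ± 0.07 for Il2ra and 5.60 for Cadm1. Glycolysis was lower in 19 of 20 genes in each (medians -1.16 and -1.04) and IL-2-STAT5 targets in 20 of 20 (medians -2.06 and -1.79). Ribosome biogenesis was higher, in 28 and 29 of 29 genes (medians 0.88 and 1.02), with Myc at -0.66 ± 0.07 and -0.36 ± 0.07, while ribosomal proteins were lower in 34 and 33 of 35. Calls were 7132 and 7069 of 12392 genes. Adjusted over the list alone the counts were 19 and 19 for glycolysis, 20 and 20 for IL-2-STAT5 targets, 28 and 29 for ribosome biogenesis, and 34 and 33 for ribosomal proteins. None of these lists kept its call when correlation was estimated: adjusted p = 0.34 and 0.37 with an estimated correlation for glycolysis, 0.2 and 0.2 for IL-2-STAT5 targets, 0.47 and 0.42 for ribosomal proteins, and 0.35 and 0.37 for ribosome biogenesis. Wild-type libraries held 8.8 and 8.9 M counts and the others 10.2 to 21.7 M, and thinning all to the smallest left 6699 and 6579 calls. The ribosomal RNA transcript Rn45s stood at 2095.3 and 2280.8 CPM in wild type and at 3235.5 to 6793.2 in the other 4 libraries, and Lars2 at 204.7 and 253.8 against 645.5 to 1395.4. A difference in RNA preparation between the genotypes is therefore not excluded. The myeloid marker Cd68 was lower in each genotype (-1.67 and -1.51) and Cd74 in the Stat5a-null one (-2.60), and whether other cells carry them was not tested.

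Between these 2 genotypes, 312 genes differed (150 higher in Stat5b-null). Apart from Stat5a (4.43) and Stat5b (-0.89), Cd74 (2.51), the pyruvate dehydrogenase kinase Pdk1 (1.42) and the Treg factor Ikzf2 (1.19) were higher in the Stat5b-null cells, and the protease Ctse (-3.47) and Atp10d (-1.97) lower. Ikzf2 lost its call without replicate 2 of the Stat5a-null (0.98) or the Stat5b-null (1.07) genotype. Il2ra was not called (-0.04 ± 0.07, adjusted p = 0.87). Glycolysis was higher in the Stat5b-null cells in 3 of 20 genes (median 0.22; 12 adjusted over the list alone; camera adjusted p = 2.5e-07, and adjusted p = 0.52 with an estimated correlation). That count became 7 with DESeq2, 6 with the replicate block, 11 without the low-count filter and 2 with only the libraries compared. Without the low-count filter 826 genes were called, and the count was 102 and 162 without Stat5a-null replicates 1 and 2 and 168 without Stat5b-null replicate 2.

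**Figure D4:**
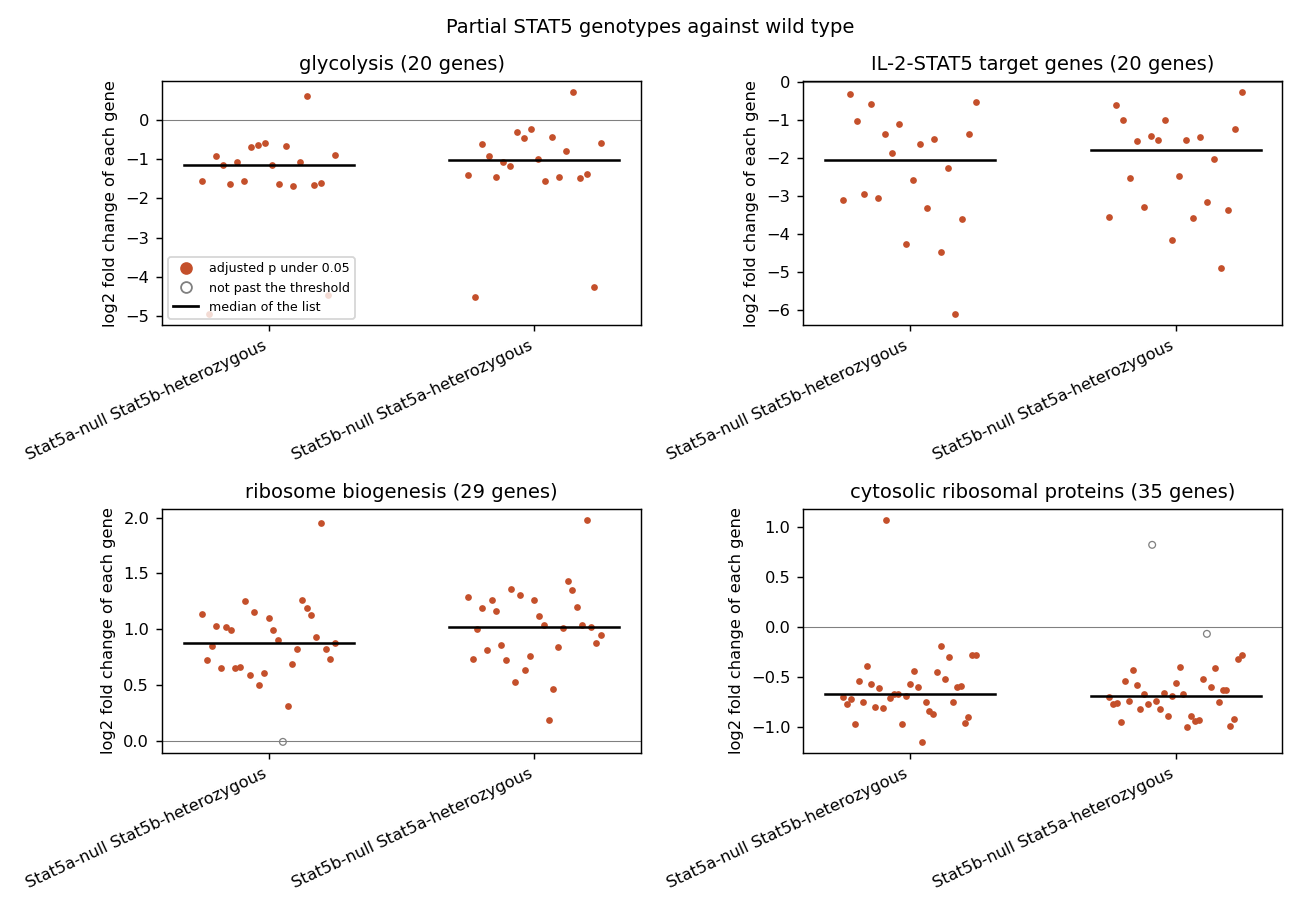
Log2 fold changes against wild type of single genes in 4 lists for the 2 reduced-dose genotypes (AAB, Stat5a-null Stat5b-heterozygous; BBA, Stat5b-null Stat5a-heterozygous). Filled points have an adjusted p below 0.05, open points do not, and the black line is the list median.

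STAT5 itself was mapped by chromatin immunoprecipitation in 2 replicates of T cells cultured 5 days with IL-2, and so was p300, the acetyltransferase found at active enhancers. The STAT5 lists hold 26477 and 19320 peaks, of which 11213 peaks of replicate 1 (42.3%) overlap a replicate 2 peak. The p300 lists hold 10716 and 17762 peaks, and 4498 of the first (42%) overlap the second. Of the 11213 shared STAT5 sites, 3603 (32.1%) lie on a shared p300 site, and 82.4% of shared p300 sites carry STAT5. Random shifts of the peaks gave a mean of 17 and at most 179 such sites. Shifted peaks are not kept at active sites, so the excess need not be particular to STAT5 and p300. The p300 share climbed with STAT5 peak height, from 6.7% through 11.4% and 18.6% to 41.6% over 4 equal groups of the 19320 replicate 2 peaks. Peak width was not held fixed, and wider peaks meet others more readily at 1 shared base. The tallest peak was 3676 bases wide, against a median of 259 in that list. The tallest STAT5 site spans positions 23986214 to 23989890 of chromosome 16 (2551.8 normalised tags, 32.91-fold over input in the deposited list). Peaks could not be assigned to genes, since the mouse genome annotation the positions refer to was not at hand. Asking for 50% reciprocal overlap left 7711 shared STAT5, 2901 shared p300 and 1502 joint sites. Replicate 2 lists used a stricter Poisson threshold for the peak itself and a laxer one over input than replicate 1, so the list lengths cannot be compared directly.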

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

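Tests of leftover Stat5 transcript, wild-type baseline and Myc level were chosen only after the glycolysis result was seen, and the counts of other splits of the samples were planned.

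Vector effects that differ between genotypes stand out because the difference itself was tested. The STAT5, AKT and MYC vectors each raised their own gene by a larger fold in deficient cells, so dose and genotype are not separated. The STAT5 vector acted differently in the 2 genotypes on 7425 genes, led by Lrrc32 (5.80) and Socs2 (5.13). The AKT vector did so on 1727, with P2rx7 (2.11) and Ndrg1 (-2.21) at the 2 ends, and the MYC vector on 206, with Ifrd2 (1.68) high. STAT5 loss acted differently between the 5 culture conditions on 2769 genes, Hk2 among them. Each of these counts is at an adjusted p below 0.05 in edgeR.

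Other splits of the same libraries were counted with only the libraries compared and with set or culture condition as a block, so real values here differ from the counts above. Each share counts the real split itself, so 1 of 100 is the lowest that 100 splits can give. STAT5 loss with control vectors had that share (real 9279, highest other 227), so no other split drawn called as many genes. Such a share makes chance unlikely but does not exclude it. The same share held for the STAT5 vector in deficient cells (9163, highest other 6484) and in wild type (2020, highest other 922). It also held for deficient cells with the STAT5 vector against wild type (4892, highest other 655). For AKT by genotype, 1 of 100 splits was as large (781, highest other 659), and for STAT5 by genotype 2 of 100 (6415, highest other 7098). Splits for differences between genotypes exchanged vectors within each genotype, so many of them still carry a vector effect. They cannot decide on chance for these counts. In set 4, 1 of 69 splits of the average was as large (2728, highest other 571). Splits that part every pair of same-numbered libraries, 37 in all, gave at most 1164 apart from the real one. For MYC by genotype, 9 of 100 splits gave as many genes (real 1, highest other 102), so chance is not excluded for that count.

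Splits were too few for a share under 0.05 in 5 comparisons. These were IL-2 against rest (10 splits; real 9942, highest other 0; 1 as large), MYC in deficient cells (18 splits; 1897, highest other 8; 1 as large), AKT in deficient cells (4687, highest other 6; 1 as large) and AKT in wild type (1144, highest other 12; 1 as large). MYC in wild type gave 0 in the real split, so 18 of 18 were as large. The highest other split there, at 1945, follows the replicate number, which goes with the sex of the mice, and with the replicate block the MYC count was 228.

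Glycolysis genes were lower on STAT5 loss in iTreg (median -1.89) and Th0 (-0.77) cultures, with medians of 0.38 in Th1, -0.19 in Th2 and 0.03 in Th17, where the mean was -0.04, although Th0 differed from Th2 in 4 and from Th17 in 2 of 20 genes. With an estimated correlation camera gave adjusted p = 0.039 in iTreg and 0.059 in Th0. With the replicate block these were 0.053 and 0.11. Incomplete deletion in Th1, Th2 and Th17 is argued against, since Stat5a plus Stat5b there reached at most 1.16% of wild type. A lower start in wild-type cells is argued against too, the lowest wild-type list median lying at -0.15 from Th0. Myc was at -1.46 in iTreg, -1.05 in Th0 (adjusted p = 0.052; called in 4 alternative fits) and 0.41 in Th1 (adjusted p = 0.44) and cannot be told apart as a cause, since set 4 has no vector and the MYC vector moved the list by a median of 0.18 in other cultures. Cytokines that act through other signals in Th1, Th2 and Th17 cultures may keep these genes on without STAT5, which was not tested.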

How the results depend on the processing

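Fits without the 5 doubted libraries, with sex as a covariate in set 1, with set 7 thinned, and overlap lists with 1 library left out were chosen only after seeing the data, and the other alternatives were planned. Apart from leaving out 1 library, 165 of 210 values of the 41 summary results kept their direction and side of the threshold, or stayed within 1.5-fold for counts. Of the genes named, 1428 of 1462 such values kept direction and call, 17 lost the call, 17 gained it and 0 reversed. Calls for IL-2 ran from 9056 to 10677, for STAT5 loss with control vectors from 9084 to 9978 and for the STAT5 vector in deficient cells from 8941 to 10259. The cause of the moves below was not tested.

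Counts of calls moved by over 1.5-fold as follows. DESeq2 gave 438 for MYC in wild type (130), 410 for MYC by genotype (206), 1 for CD25 in deficient cells (0), 127 and 179 for AKT added to STAT5 in deficient cells (62) and wild type (80), and 1772 and 1385 for MYC added to STAT5 (984 and 732). It gave 1635 in Th0 (993), 2816 in Th1 (1796), 1166 in Th17 (747), 4684 for the differences between culture conditions (2769) and 2451 in Treg cells (3701). No low-count filter gave 130 for MYC by genotype, 1 for CD25 in deficient cells and 826 between the reduced-dose genotypes (312). Fitting only the groups compared gave 1 for MYC by genotype, 1540 for AKT in wild type (825), 1 for CD25, 4 and 126 for added AKT, 2598 and 2214 for added MYC, 871 in Th1 and 803 in Th2 (1765), with fewer libraries to estimate the spread. Without the doubted libraries, MYC in wild type gave 413, MYC by genotype 643, CD25 1 in deficient cells and 1 by genotype (0), added AKT 26 and 146, and added MYC 1554 and 1312. Gene list calls fell from 362 to 30 with an estimated correlation.

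The replicate block gave 2994 in Th2, where the numbers pair the samples. In set 4 lists, of 168 tests, the preset lost 2 calls and gained 1 and the estimated correlation went from 3 calls to 5: glycolysis in iTreg went from 0.039 to 0.053, fatty acid synthesis from 0.13 to 0.031 in Th0 and from 0.094 to 0.047 in iTreg, and Th2-associated genes in Th17 from 0.21 to 0.046. The other counts of set 4 rose by less than 1.5-fold. They were 1386 in Th0 (993), 2342 in Th1 (1796), 1071 in Th17 (747) and 4254 in iTreg (3457). The average gave 5533 (4152) and the differences between culture conditions 3879 (2769). In Th2 the block called 10 oxidative phosphorylation genes higher (5) and 9 for ribosome biogenesis (5). Where libraries share a number in part or whole without passing the check, the block gave 228 for MYC in wild type, 1 for CD25 in deficient cells, 110 and 174 for added AKT and 549 between the reduced-dose genotypes. It gave 9873 for IL-2, 5310 in Treg cells, and 7548 and 7509 for the reduced-dose genotypes. Libraries correlated best with their own number in 6 of 6 in set 1, 14 of 16 in set 3, 20 of 24 in set 5, 4 of 4 in set 6 and 6 of 6 in set 7. In groups of 2 both libraries always give the same answer, so these libraries are not independent. In set 1 the same-number correlations were only 0.01 to 0.03.

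Leaving out 1 library leaves a group of 1, assumed to vary like the others. For summary results, 326 of 388 such values held, and for named genes 1910 of 2008, with 96 calls lost. Ranges with a move over 1.5-fold were 1731 to 3306 for STAT5 in wild type, 1073 to 1984 for MYC in deficient cells, 4 to 132 for MYC in wild type, 376 to 785 for AKT in wild type, 865 to 2150 for AKT by genotype and 0 to 1 for CD25 in deficient cells (1 without set 3 control replicate 2). Added AKT gave 9 to 340 and 1 to 10, and added MYC 21 to 522 and 7 to 844. In set 4 they were 423 to 594 for Th0, 488 to 1299 for Th1, 734 to 1577 for Th2, 266 to 635 for Th17, 1550 to 2339 for iTreg and 1750 to 3393 for the differences between conditions. The reduced-dose genotypes gave 102 to 261. MYC by genotype ran from 39 to 357. Its moves came without set 2 wild-type control replicate 2 (109) and MYC replicates 1 (82) and 2 (72), set 2 deficient control replicate 2 (63) and MYC replicates 1 (118) and 2 (133), set 5 deficient controls 1 (357) and 2 (39) and MYC replicate 2 (95), and set 5 wild-type control 1 (49) and MYC replicates 1 (101) and 2 (95). Dapl1 and Srm lost their call in wild type with MYC in 7 of 8 such fits, and Gzmb in wild type with AKT in 6 of 8.

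In the overlaps, holding the STAT5-dependent list to genes at least 2-fold lower reversed the lean for MYC (4.21%) and AKT (7.1%). The AKT share ran from 17.1 to 25.8% with 1 library left out and lost its test without deficient Th1 replicate 2 (18.2%). Reciprocal overlap of 50% left 2901 shared p300 peaks (4498) and 1502 joint sites (3603). The stronger part of the replicate 2 list left 7107 shared STAT5 peaks (11213) and 2378 joint sites. That choice was not run on replicate 1, which has no heights, and the test of STAT5-bound genes was not run for want of an annotation. Depth limits set 3 wild type with STAT5 replicate 2, at 3.9 M counts, and thinning set 7 left 6699, 6579 and 248 calls.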

Other observations

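Tests of mixing, wrong labels, pooling, depth and Myc level in these paragraphs were chosen only after the results were seen.

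Growth and energy genes beyond glycolysis did not change alike across the sets. On STAT5 loss with control vectors, oxidative phosphorylation genes were lower in 67 of 71 (67 adjusted over the list alone), nucleotide synthesis in 20 of 20 (20) and cell cycle genes in 29 of 30 (29). With an estimated correlation camera gave adjusted p = 0.27, 0.076 and 0.15 for the 3 lists. IL-2 raised 68 of 71, 20 of 20 and 29 of 30 of the same lists, with adjusted p = 0.22, 0.22 and 0.29 with an estimated correlation. In set 7, nucleotide synthesis was instead higher in 15 of 20 genes in the Stat5a-null and 14 in the Stat5b-null genotype (15 and 14 adjusted over the list alone; adjusted p = 0.39 and 0.37 with an estimated correlation). Oxidative phosphorylation genes in the Stat5a-null genotype were higher in 27 and lower in 9 (26 and 9 adjusted over the list alone), and in the Stat5b-null genotype higher in 21 and lower in 15 (21 and 14), with no list shift by camera (adjusted p = 0.3 and 0.61, and adjusted p = 0.89 and 0.92 with an estimated correlation). In Th2 cultures 5 oxidative phosphorylation genes were higher and 1 lower on STAT5 loss (1 and 1 adjusted over the list alone; 10 and 1 with the replicate block; adjusted p = 0.9 with an estimated correlation). In iTreg 28 of the 71 were lower and 0 higher, and in the average of the 5 conditions 10 and 0 (35 and 6 lower adjusted over the list alone; adjusted p = 0.39 and 0.77 with an estimated correlation). With the replicate block 33 were lower in iTreg and 17 in the average.

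Some genes of other T cell states changed in several sets, not always in the direction of STAT5. Bcl6, which drives follicular helper cells, was higher on STAT5 loss in each of the 5 culture conditions (2.67 in Th0, 2.43 in Th1, 3.80 in Th2, 3.24 in Th17 and 3.61 in iTreg) and in the 2 reduced-dose genotypes (2.20 and 2.23). It fell when STAT5 was added to AKT (-3.36) or MYC (-3.40). The Treg factor Foxp3 rose with STAT5 in those 2 settings (3.74 and 3.65). Sox4 was higher on STAT5 loss (3.87) and stayed above wild type with the STAT5 vector (4.59). Cd24a rose with the STAT5 vector in deficient cells (5.44) and also on STAT5 loss in Th1 (4.74) and Th17 (4.21) cultures. Treg-associated genes were lower in 9 of 10 in the Stat5a-null and 9 of 10 in the Stat5b-null genotype (9 and 9 adjusted over the list alone; adjusted p = 0.34 and 0.37 with an estimated correlation).

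The library of wild-type cells with the STAT5 vector in set 3, replicate 2, holds transcripts of both sexes (Xist at 1295.0 and Ddx3y at 71.8 CPM) and less Stat5a than replicate 1 (138.4 against 608.0). RNA of STAT5-deficient control cells from a female mouse may have been mixed in. For 13 genes that mark those cells, the library stands at a median share of 25.5% of their level (quartiles 22.0 to 26.1), against -1.4 to 1.3% in the other 7 wild-type libraries of the set, and Xist alone gives 26.5%. A wrong label for the whole library is argued against by Stat5b at 156.7, where deficient controls reach 2.9, and pooling of wild-type mice of both sexes by the lower quartile of 22.0%. Such a share does not account for all of the lower Stat5a, and the rest was not tested.

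Ribosome biogenesis genes were higher in the 2 reduced-dose genotypes of set 7 (medians 0.88 and 1.02) and lower on full STAT5 loss in cells with control vectors (-1.35), while ribosomal proteins were lower in set 7 (median -0.67 in Stat5a-null cells). Camera called none of these lists with an estimated correlation. In set 7 it gave adjusted p = 0.35 and 0.37 for ribosome biogenesis, and 0.47 for ribosomal proteins in Stat5a-null cells. Full loss in set 4 gave medians of -0.40 in Th0, where 1 of 29 genes was lower, 0.54 in Th2, where 5 were higher (9 with the replicate block) and 0 lower, and -0.68 in iTreg, where 16 were lower (1 in Th0, 11 up and 1 down in Th2, and 20 in iTreg adjusted over the list alone; adjusted p = 0.43, 0.9 and 0.3 with an estimated correlation). The lower of the 2 medians was 0.90 after thinning. Thinning at random leaves expected fold changes as they were, so this cannot decide whether fewer counts in the wild-type libraries play a part. More Myc transcript is argued against, with Myc no higher than -0.36. Gene dose, culture and RNA preparation (Rn45s at 3235.5 to 6793.2 CPM against 2095.3 and 2280.8 in wild type) stay open, and none was tested.

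Replicate number went with the sex of the mice in sets 2 to 6, by Xist and Ddx3y. In set 1, rested replicate 1 carried Xist and replicates 2 and 3 Ddx3y, while the 3 IL-2 libraries carried Xist, so sex is partly tied to treatment there. Set 7 libraries carried Xist throughout.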
